A study of Mus musculus with 16 samples.

How the data were processed

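RNA was measured in 16 libraries of cultured mouse bone marrow stromal progenitors, 4 in each of 4 groups given by the labels: WT and KO at day 3, and WT and KO at day 7. Here KO stands for libraries labelled KO. The replicate names are those of the sample titles (1, 1b, 3 and 4 for WT day 3, 5 to 8 for KO day 3, 9, 10, 10b and 11 for WT day 7, and 13 to 16 for KO day 7). The libraries were poly(A)-selected and strand-specific, and were read as paired ends on an Illumina sequencer, per the labels' protocols. The labels give RNA integrity numbers from 9.3 to 10 for the libraries, while the protocol text gives a lower range.

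The raw count columns hold whole numbers of reads per gene, not normalised, as the authors deposited them per the file headers. The submitters' processing notes name STAR 2.4.2a, featureCounts, edgeR and the mouse build mm10 without saying what each was used for, and the gene annotation is not given in the sources used here. The columns the file headers call CPM hold a signal that the authors made by dividing each count column by 1 constant, an effective library size. Those deposited columns sum to between 741758 and 1341926. The implied size was 1.181 to 1.209 times the total count in the WT day 3 group, 0.77 to 0.83 in the day 3 group labelled KO, 1.249 to 1.348 in WT day 7 and 0.745 to 0.841 in the day 7 group labelled KO. Gene lengths in bases were deposited beside them and served only to describe Zfp384. The authors' scaled columns entered no main test, and every value reported as CPM was computed anew from the counts. How a read that matches several copies of a gene was counted is not given in the sources used here, so members of near-identical families are uncertain singly.

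The table holds 13474 genes, and every gene has a summed count of at least 105 over the libraries, so genes of lower count were not analysed here. In it 22 symbols had turned into dates and 1 symbol occurs more than once, and none of these is named. It holds 5 genes of the Y chromosome and 0 mitochondrially encoded genes, so the list of mitochondrially encoded genes had 0 measured members. No column of values per library was left without its library. Total counts per library ran from 31285188 to 47635039, and 63 to 150 genes per library were at 0. The common dispersion was 0.00181, a coefficient of variation of 4.25% between wells beyond counting error, so small differences pass the test at this depth. A count of 0 over a group was read as fewer than the floor of 3 counts, and such floors cover counting error only.

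Libraries whose titles share a number were compared before they were averaged. Over genes with a summed count of at least 20 in the libraries of a pair, the chi-square per degree of freedom was 2.89 for WT day 3 libraries 1 and 1b. It was 4.74 for WT day 7 libraries 10 and 10b. The other 22 pairs within groups had 2.33 to 17.88. The highest values were those of library 15 of the day 7 group labelled KO, 17.88 with library 13 and 16.47 with library 14. What the b stands for is not given in the sources used here, and these values do not show whether the libraries of a pair came from separate wells. Both pairs that share a number differed by more than sampling noise and entered as separate libraries, with their summed counts as an alternative.

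Counts were fitted in R 4.3.3 with edgeR 4.0.16, with trimmed mean of M values (TMM) factors of 0.949 to 1.05. The robust quasi-likelihood model had 4 group means over all 16 libraries, 12 residual degrees of freedom and a median of 15.54 prior degrees of freedom. The filter filterByExpr removed 0 genes. The 5 comparisons were KO against WT at each day, day 7 against day 3 in each genotype, and the genotype by day interaction. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes, and a further count asks for a change of at least 2-fold. There were 30 gene lists, and the 28 with at least 3 measured members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists of a comparison. The same test with a correlation estimated per list, and fry, were alternatives. CPM are counts divided by the TMM-scaled library size.

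The text names Zfp384. It names per comparison the 6 highest and the 6 lowest log2 fold changes among called genes with at least 10 CPM in the higher group and no overlap between groups, leaving out model and clone names. For the interaction the highest of the 4 groups had to reach 10 CPM and no overlap was asked. It names per list up to 4 called members with the largest absolute change and at least 1 CPM in the higher group. It also names anchor genes chosen with the lists, such as Runx2, Alpl, Pparg, Sox9, Myc, Ddit3, Mki67, Ptprc, Igf1 and Xist. Some genes that the rule names are not reported here. A gene named outside this rule is said to have been chosen after its values were seen.

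Chromosome medians were taken over the genes of each chromosome, for the whole chromosome and, on the autosomes, for 8 parts of equal length. They were set against 10000 shuffles of genes over the autosomes. Called genes within 10 Mb of Zfp384 were compared with draws of genes of like expression elsewhere. Other splits of the libraries were fitted with the same model, 35 for each pair of groups and 100 draws for the interaction.

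The code was tested on simulated data drawn from the means and library sizes of these libraries, with 200 genes seeded and divided over changes of 1.5-fold, 2-fold and 4-fold. At 2-fold it called 65 of 66 genes (98.48%) for KO against WT at day 3 (13465 genes in the fit) and 65 of 67 (97.01%) at day 7 (13464). It called 60 of 65 (92.31%) between the days in WT (13463), 62 of 65 (95.38%) in KO (13464) and 63 of 66 (95.45%) in the interaction (13461). At 1.5-fold it called 57 of 65, 60 of 66, 58 of 64, 55 of 65 and 52 of 67 genes in the same order, and of unchanged genes at most 0.2%. A seeded list was called in all 5 comparisons, beside at most 1 other list. The simulated genes were drawn independently of each other, so this does not test camera on lists whose genes are correlated. Far fewer genes were changed than differ in the real data, so the simulation does not test the scaling there either. A chromosome shift of 0.5 simulated over 492 genes was recovered as 0.493 at day 3, where the largest of the others was 0.012.

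The alternatives were RLE size factors, total counts only, TMM without the 20 genes of highest mean count, no filter, a filter of at least 1 CPM in at least 4 libraries, DESeq2 1.42.0, limma-voom, a glmTreat test against a 1.5-fold change, a fit of the compared groups alone, the summed pairs, and leaving out each library in turn. Chosen after the data were seen were the authors' effective library sizes, each library centred on the median of each chromosome with at least 20 genes (with a prior count of 2), and leaving out the genes of shifted chromosomes. Tables and plots used numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Counts per exon, reads and sequence variants were not analysed here.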

Results

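RNA was profiled from mouse mesenchymal stem/progenitor cells (MSPCs), adherent marrow stromal cells that can give rise to bone, cartilage and fat cells. The C57BL/6 cells, at passage 5 to 10, were labelled wild type (WT) or knockout (KO) for Zfp384, which encodes the zinc finger transcription factor Nmp4. At day 3 they had been seeded sparsely and kept in a medium that does not induce differentiation. At day 7 they had been seeded more densely and had received ascorbic acid, dexamethasone (a synthetic glucocorticoid) and glycerol 2-phosphate from 48 hours, which makes them early osteogenic cultures. Each of the 4 groups of genotype and day held 4 libraries, 16 in all. The labels code libraries by well, but what the b in the replicate names 1b and 10b (WT, day 3 and day 7) stands for is not given in the sources used here. The series text gives 4 technical replicates and 1 biological replicate per condition, so p-values measure only the spread between wells, and a difference between genotypes is also a difference between cultures. Poly(A) strand-specific libraries gave counts for 13474 genes. Total counts per library were 36133472 to 47635039 in the WT day 3 group and 31285188 to 38093753 in the day 3 group labelled KO. They were 33980456 to 36528132 in the WT day 7 group and 32919372 to 41440013 in the day 7 group labelled KO. The 10 genes with the most counts took 6.64 to 6.80%, 7.83 to 8.36%, 7.27 to 7.53% and 12.11 to 12.85% of the counts in these groups. Levels are given as CPM (counts scaled by library size, mean ± SD of the 4 libraries of a group). Log2 fold changes and interactions carry an approximate standard error. This error is not reliable where a group holds few counts, and can be smaller than counting error alone. Aldh1a2 had 7, 3, 2 and 1 counts in the day 3 libraries labelled KO, too few for the error printed with it.

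Zfp384, the targeted gene, lies on chromosome 6 from 125009238 to 125037870 on the plus strand, in the coordinates of the deposited table, with 13 exon entries and a summed exon length of 3553 bases. At day 3 it was at 80.6 to 84.0 CPM in the 4 WT libraries and at 89.7 to 93.5 CPM in the 4 labelled KO, and at day 7 at 83.8 to 91.3 and 111 to 122 CPM. Every library labelled KO was above every WT library of its day. The group means stood at 81.8 ± 1.54 CPM in the WT and 91.5 ± 1.74 CPM in the group labelled KO at day 3, and at 88.1 ± 3.17 and 117 ± 5.04 CPM at day 7. The log2 fold change was 0.16 ± 0.04 at day 3 and 0.41 ± 0.04 at day 7 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.000139 and 9.42e-12). Neither was past a test against a 1.5-fold change (glmTreat adjusted p = 1 at both days), with trimmed mean scaling. The size depends on the scaling: the log2 fold change was 0.66 and 0.99 with the authors' library sizes, and 0.56 and 0.74 relative to the median of chromosome 6, both chosen after the data were seen. Counts per exon were not analysed here, so whether the RNA was intact could not be read from these values. The RNA was not lower in the libraries labelled KO, and counts of the whole gene can neither bear out nor contradict the label. The groups are therefore called libraries labelled KO throughout, and every direction between genotypes rests on the labels alone.

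**Figure D1:**
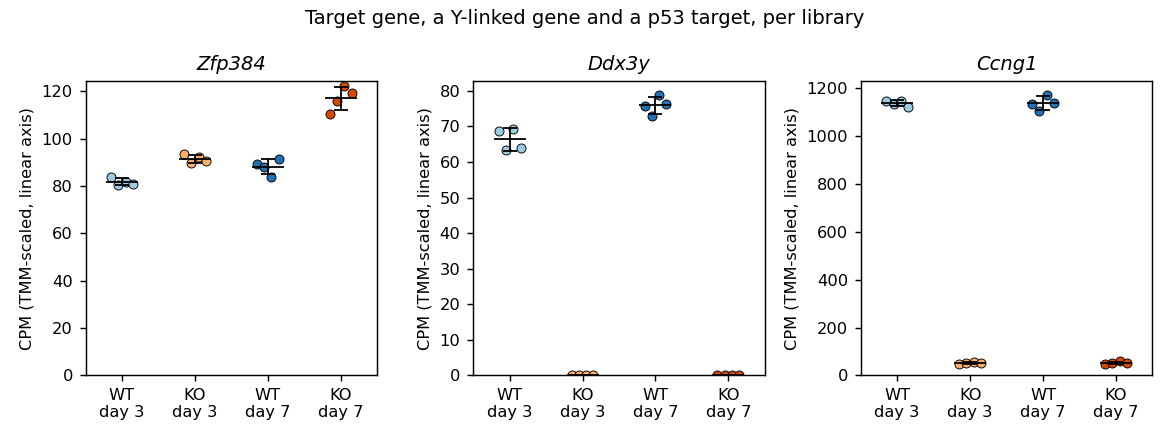
CPM on a linear axis from 0 of Zfp384, the Y-linked gene Ddx3y and the p53 target Ccng1 in each of the 16 libraries (points), with the mean (bar) and SD (error bar) of the 4 libraries of each group. Zfp384 is higher in libraries labelled KO (91.5 against 81.8 CPM at day 3), while Ddx3y falls from 66.3 to 0.0967 CPM and Ccng1 from 1138 to 51.6 CPM.

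At day 3 the question was which RNAs differ between cells labelled KO and WT before osteogenic induction. In the libraries labelled KO 20 of 21 genes of the integrated stress response, in which translation is slowed, rose and 1 fell (median log2 fold change 1.48, camera adjusted p = 1.5e-12, adjusted p = 0.13 with an estimated correlation). Of 16 genes in the list of p53 targets and senescence genes (the p53 and senescence list) 12 fell and 4 rose (median -1.87, camera adjusted p = 1.5e-12, and 0.00017 with an estimated correlation). The 4 that rose, named after their values were seen, were the senescence genes Cdkn2a and Cdkn2b, Gdf15 and Plk2. Trib3, a pseudokinase induced by the stress factors ATF4 and CHOP, rose from 8.14 ± 0.338 to 80.2 ± 2.47 CPM, a log2 fold change of 3.30 ± 0.06 (n = 4 libraries per group). Ccng1, which encodes the p53-induced cyclin G1, fell from 1138 ± 13.4 to 51.6 ± 2.86 CPM, and Eda2r, another p53 target, from 96.1 ± 1.99 to 1.05 ± 0.177 CPM. Among cartilage genes Col2a1, the main collagen of cartilage, fell from 4634 ± 251 to 35.4 ± 5.39 CPM. Acan, its main proteoglycan, was at 0 counts in the WT libraries and at 2.07 ± 0.206 CPM in those labelled KO, at least 116-fold higher against a floor of 3 counts over the group.

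The genes with the widest differences at day 3 went from near absence to clear expression. Ankrd1, a target of the mechanosensitive coactivators YAP and TAZ, rose from 0.332 ± 0.108 to 348 ± 14 CPM (10.04 ± 0.10). Fndc3c1 was at 0 counts in the WT libraries and at least 633-fold higher in those labelled KO, and Tcfl5 stood at 0.0119 against 22.4 ± 0.937 CPM. Gng10, a G protein gamma subunit, rose to 48.9 ± 3.23 CPM from 0.185 ± 0.117. Rps4l and Pcdhga12 rose to 16.1 ± 1.25 and 15.5 ± 0.90 CPM from 0.134 and 0.129 CPM, and as members of multigene families both are uncertain, since counting could have split their reads. In the other direction Aldh1a2, which makes retinoic acid, fell from 112 ± 2.77 to 0.0937 ± 0.0727 CPM (-10.13 ± 0.10). Ano3, an anoctamin membrane protein, fell from 96.3 ± 1.91 to 0.043 ± 0.049 CPM and Svop from 111 ± 3.83 to 0.0825 ± 0.0635 CPM. Plcd4 and Anks1b stood at 0.0146 and 0.0149 CPM in the libraries labelled KO against 39.8 ± 1.55 and 20.4 ± 0.621 CPM.

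Of the lists of genes, fixed like the tests and the rule for named genes before the data were examined, 7 were called at day 3. All 18 measured macrophage and myeloid markers fell (median log2 fold change -2.50, camera adjusted p = 0.00058, adjusted p = 0.21 with an estimated correlation). Adgre1, which encodes F4/80, fell from 8.21 ± 0.84 to 0.591 ± 0.195 CPM and Lyz2, lysozyme, from 74.9 ± 4.87 to 19.7 ± 3.05 CPM. Further p53 and senescence list members with wide falls were Trp53inp1, which promotes p53 activity (-4.58 ± 0.08), and Btg2, an antiproliferative gene (-3.90 ± 0.05). In the integrated stress response list Vldlr, a lipoprotein receptor, went from 3.59 ± 0.398 to 68.6 ± 2.07 CPM and the cystine transporter gene Slc7a11 from 1.43 ± 0.323 to 22.0 ± 1.05 CPM. Ribosome biogenesis genes rose in 27 of 30 cases and fell in 2 (median 0.72, camera adjusted p = 3e-06, adjusted p = 0.15 with an estimated correlation). Among them Myc rose from 80.8 ± 3.39 to 211 ± 4.30 CPM. The nucleolar protein genes Ncl (log2 fold change 0.72 ± 0.04) and Nop16 (1.27 ± 0.05) and Fbl, the methyltransferase fibrillarin (1.16 ± 0.04), rose as well. Cell cycle genes rose in 30 of 37 cases and fell in 1 (median 0.46, camera adjusted p = 0.0034, adjusted p = 0.21 with an estimated correlation). Mki67, the Ki-67 proliferation marker, rose from 202 ± 6.54 to 422 ± 19 CPM. Rrm2, a ribonucleotide reductase subunit, fell from 448 ± 6.58 to 194 ± 4.30 CPM.

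Stromal progenitor markers split, with 8 of 22 higher and 12 lower (median -0.60, camera adjusted p = 0.019, adjusted p = 0.13 with an estimated correlation). Cxcl12, the chemokine that retains blood stem cells in marrow, fell from 4831 ± 98.8 to 848 ± 27.5 CPM. Thy1 (CD90) fell from 12.7 ± 0.401 to 0.0877 ± 0.0352 CPM and the transcription factor Ebf3 from 21.9 ± 0.846 to 0.147 ± 0.0927 CPM, and the leptin receptor Lepr rose from 0.052 ± 0.0308 to 4.52 ± 0.413 CPM. All 5 sex-linked genes measured fell (median -1.19, camera adjusted p = 0.0016, adjusted p = 0.21 with an estimated correlation). Ddx3y, a Y-linked RNA helicase, fell from 66.3 ± 3.12 to 0.0967 ± 0.0436 CPM. Kdm5d fell from 50.1 ± 2.24 to 22.0 ± 1.32 CPM and Uty from 21.9 ± 2.46 to 10.8 ± 1.14 CPM. Eif2s3y, outside the rule for named genes and added after its values were seen, went from 49.5 ± 1.68 to 25.5 ± 1.49 CPM. Xist, the RNA that silences the inactive X chromosome, was low in both (1.12 ± 0.389 and 0.0568 ± 0.0442 CPM).

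Osteoblast genes were not called as a list at day 3 (7 of 25 higher, 13 lower, median -0.47, camera adjusted p = 0.84). Phospho1, a phosphatase that starts mineral deposition, rose from 1.5 ± 0.0449 to 12.4 ± 0.432 CPM and Postn (periostin) from 329 ± 10.4 to 2070 ± 41.1 CPM. Smpd3, a sphingomyelinase needed for mineralisation, fell from 108 ± 2.94 to 6.30 ± 0.528 CPM and Sp7 (osterix) from 77.7 ± 1.96 to 41.0 ± 3.12 CPM. Alpl, the tissue-nonspecific alkaline phosphatase, stood at 129 ± 5.83 and 121 ± 18.1 CPM (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.457). Runx2, the master regulator of the osteoblast lineage, rose by 0.36 ± 0.04. Adipocyte genes were split as well (8 of 17 higher, 7 lower, camera adjusted p = 0.093). Fabp4, a fatty acid carrier, fell from 113 ± 3.24 to 3.77 ± 0.466 CPM and Pparg, the master regulator of fat cells, from 51.8 ± 1.74 to 10.6 ± 0.42 CPM. Mmp13, the collagenase of bone and cartilage, fell from 273 ± 10.4 to 17.6 ± 1.02 CPM within a protease list of 6 higher and 9 lower genes (camera adjusted p = 0.15). Of the 7 osteoclast markers 2 rose and 4 fell (camera adjusted p = 0.073), with Acp5, the phosphatase TRAP, at -4.51 ± 0.23. Of 25 interferon-stimulated genes 20 fell and 1 rose, without a call as a list (median -1.59, camera adjusted p = 0.084). Macrophage markers were lower at both days, but at day 7 interferon-stimulated genes rose in 15 cases and fell in 5 (median 0.59, camera adjusted p = 0.41). Osteoclast markers rose in 2 and fell in 3 at day 7 (camera adjusted p = 0.79).

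Across all genes, 11638 differed at day 3, 5788 higher and 5850 lower in the libraries labelled KO, and 3905 by at least 2-fold (1583 higher, 2322 lower; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05). The remaining lists (for example unfolded protein response, 15 of 23 higher and 5 lower, camera adjusted p = 0.32) were not called. With each chromosome centred on its median, an alternative chosen after the data were seen, the unfolded protein response was called higher (17 higher, 2 lower, camera adjusted p = 0.014), and adipocyte (0.038), osteoclast (0.03) and interferon-stimulated genes (0.05 after rounding) were called lower. Every list count in this comparison but that of the Wnt pathway (11 higher and 10 lower, 11 and 12 adjusted over the list alone) was the same adjusted over the list alone. All changes are relative to the median gene. With the library sizes implied by the authors' own scaled columns the median log2 fold change between genotypes was 0.49 at day 3 and 0.55 at day 7, against 0.00 and -0.03 with trimmed mean scaling. That moves the share of called genes that were higher from 49.7 to 72.9% and from 48.5 to 75.4%. Total counts only, a planned setting, moved it the other way, to 45.5% at day 3 and 41% at day 7. Of the 7 list calls, that of the p53 and senescence list alone held with an estimated correlation.

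At day 7 the comparison asked how cells labelled KO and WT differ once osteogenic induction has begun. In the libraries labelled KO 18 of 25 osteoblast genes rose and 6 fell (median log2 fold change 1.03, camera adjusted p = 0.0088, adjusted p = 0.33 with an estimated correlation). All 23 genes of the unfolded protein response, which answers stress in the endoplasmic reticulum, rose (median 1.54, camera adjusted p = 9.6e-20, and 0.0024 with an estimated correlation). Bglap2, one of the osteocalcin genes of mature osteoblasts, rose from 5.11 ± 0.735 to 83.6 ± 8.06 CPM and Bglap from 2.58 ± 0.271 to 32.4 ± 3.95 CPM (log2 fold changes 4.03 ± 0.08 and 3.65 ± 0.11, n = 4 libraries per group). These near-identical copies are uncertain singly, since counting could have split their reads. Hspa5, the chaperone BiP, rose from 807 ± 38.6 to 6912 ± 381 CPM. Cxcl12 fell from 5914 ± 304 to 150 ± 11 CPM, and Mylk, myosin light chain kinase, from 582 ± 10.2 to 68.2 ± 3.44 CPM.

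H19, an imprinted noncoding RNA, had the highest fitted fold change at day 7 among the genes the rule names, from 0.0408 ± 0.0152 to 191 ± 58 CPM (12.07 ± 0.45). Genes at 0 counts in the WT libraries have only a lower bound and cannot be ranked against it. Ostn (osteocrin), a peptide of osteoblasts and muscle, and Cyb5r2, a cytochrome b5 reductase, were at 0 counts in the WT libraries and at least 510-fold and 603-fold higher in those labelled KO. Car6, a secreted carbonic anhydrase, stood at 0.00707 against 26.5 ± 1.40 CPM, and the receptor genes Gpr141 and Adgrd1 at 0.00661 and 0.0134 against 12.8 ± 2.07 and 20.8 ± 1.41 CPM. Svop, Ano3 and Aldh1a2 were again among the lowest, at 0.0298, 0.05 and 0.0966 CPM against 117 ± 4.38, 140 ± 4.94 and 200 ± 4.51 CPM. Ddx3y fell from 75.9 ± 2.37 to 0.0282 ± 0.0406 CPM, Lhfpl1 was at least 488-fold lower, and Ckmt1, a mitochondrial creatine kinase, stood at 21.5 ± 0.89 against 0.0138 CPM.

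Among further osteoblast genes Ibsp, bone sialoprotein, rose from 450 ± 21.2 to 1156 ± 135 CPM, Alpl from 391 ± 23.9 to 800 ± 104 CPM. Phospho1 rose from 4.90 ± 0.513 to 44.7 ± 5.40 CPM and the homeobox gene Dlx3 from 0.239 ± 0.0795 to 5.67 ± 0.506 CPM, and Sp7 fell from 173 ± 12.5 to 145 ± 14.6 CPM. By at least 2-fold 13 osteoblast genes rose and 4 fell. Sp7 was not among those 4, and its small fall may depend on the scaling. Collagen and matrix assembly genes rose in 16 of 29 cases and fell in 11 (median 0.41, camera adjusted p = 0.0077, adjusted p = 0.33 with an estimated correlation). The small proteoglycans Dcn (decorin) and Fmod (fibromodulin) rose from 1.73 ± 0.15 to 80.3 ± 5.55 CPM and from 282 ± 8.87 to 1673 ± 68.5 CPM. Col3a1, a fibrillar collagen, rose from 2086 ± 139 to 10550 ± 72.9 CPM. The contractile list fell in 13 of 14 members and rose in 1 (median -1.96, camera adjusted p = 1.6e-09, and 0.042 with an estimated correlation).

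Besides Hspa5 the unfolded protein response genes that rose included Sdf2l1, a partner of endoplasmic reticulum chaperones, from 16.4 ± 0.75 to 124 ± 10.1 CPM and the secreted stress factor Manf from 67.1 ± 2.85 to 414 ± 22.7 CPM. Integrated stress response genes rose in 20 of 21 cases and fell in 1 (median 2.79, camera adjusted p = 2.2e-29, and 0.008 with an estimated correlation). Trib3 rose from 2.69 ± 0.504 to 299 ± 18.1 CPM, Ddit3, which encodes CHOP, from 31.3 ± 1.86 to 372 ± 38.4 CPM, and Ppp1r15a, which encodes the eIF2 phosphatase subunit GADD34, from 11.7 ± 1.23 to 142 ± 9.20 CPM. Fgf21, a stress-induced hormone, was at 0 counts in the WT libraries and at least 174-fold higher. Hypoxia-responsive genes rose in 13 of 15 cases and fell in 2 (median 2.34, camera adjusted p = 2.8e-05, adjusted p = 0.39 with an estimated correlation). Car9, a carbonic anhydrase, rose from 0.39 ± 0.0611 to 70.3 ± 19.3 CPM and Ndrg1 from 5.65 ± 0.688 to 288 ± 18.1 CPM. Glycolysis genes rose in 17 of 20 and fell in 1 (median 1.11, camera adjusted p = 0.0031, adjusted p = 0.48 with an estimated correlation). The lactate exporter Slc16a3 rose from 0.493 ± 0.187 to 96.5 ± 30.1 CPM.

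Cell cycle genes went down at day 7, with 31 of 37 lower and 3 higher (median -0.79, camera adjusted p = 0.00012, adjusted p = 0.074 with an estimated correlation). Mki67 fell from 116 ± 7.15 to 63.6 ± 1.35 CPM, Top2a, a topoisomerase of dividing cells, from 234 ± 11.2 to 81.5 ± 4.43 CPM and Rrm2 from 146 ± 5.53 to 19.4 ± 1.96 CPM. The p53 and senescence list again had 12 of 16 lower and 4 higher (median -1.21, camera adjusted p = 3.6e-09, and 0.00065 with an estimated correlation). Ccng1 stood at 1138 ± 28.6 against 52.1 ± 5.51 CPM, and Phlda3 and Zmat3 at -3.10 ± 0.04 and -3.02 ± 0.04. Macrophage markers fell in 17 of 18 cases and rose in 0 (median -3.77, camera adjusted p = 0.00019, adjusted p = 0.15 with an estimated correlation). Lyz2 fell from 107 ± 7.50 to 6.70 ± 0.775 CPM. Chemokine and inflammatory genes, which macrophages also express, rose in 5 of 17 cases and fell in 12 (median -1.32, camera adjusted p = 0.0077, adjusted p = 0.2 with an estimated correlation). Stromal progenitor markers rose in 9 and fell in 13 of 22 (median -0.70, camera adjusted p = 0.0012, and 0.014 with an estimated correlation). Angpt1, an angiopoietin, fell from 71.9 ± 3.46 to 3.75 ± 0.467 CPM. Ribosome biogenesis genes rose in 26 of 30 and fell in 1 (median 0.54, camera adjusted p = 0.00038, adjusted p = 0.2 with an estimated correlation). Immediate early genes rose in 12 of 18 and fell in 4 (median 0.29, camera adjusted p = 0.044, adjusted p = 0.42 with an estimated correlation), led by the nuclear receptor Nr4a2 (3.31 ± 0.09). With each chromosome centred this list was no longer called (8 higher, 5 lower, median 0.07, camera adjusted p = 0.069). The 5 sex-linked genes fell (median -1.21, camera adjusted p = 0.0014, adjusted p = 0.15 with an estimated correlation).

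Chondrocyte genes were not called at day 7 (8 of 13 higher, 3 lower, median 1.49, camera adjusted p = 0.24). Col2a1 stood at 808 ± 27 against 16.1 ± 0.945 CPM, and Comp, cartilage oligomeric matrix protein, rose from 1.64 ± 0.357 to 38.7 ± 1.78 CPM. Adipocyte genes rose in 10 and fell in 7 of 17 (camera adjusted p = 0.72), where the median was 0.43 but the mean -0.19. Cytosolic ribosomal protein genes moved both ways (34 of 76 higher, 23 lower, camera adjusted p = 0.58). Of 5 endothelial markers 3 rose and 1 fell (camera adjusted p = 0.25), and Kdr, a VEGF receptor, rose from 0.632 ± 0.169 to 13.2 ± 0.519 CPM. Of the lymphoid and erythroid list only Lck and Epor were measured, too few for a set test, and Epor, the erythropoietin receptor, stood at 2.45 ± 0.319 against 0.024 CPM. In all, 11592 genes differed at day 7, 5618 higher and 5974 lower in the libraries labelled KO, and 4130 by at least 2-fold (1851 higher, 2279 lower; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05). List counts were the same adjusted over the list alone, and 5 of the 15 list calls held with an estimated correlation: contractile, unfolded protein response, integrated stress response, p53 and senescence, and stromal progenitor. Zfp384 RNA was not lower in the libraries labelled KO at this day either, so these directions rest on the labels alone.

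**Figure D2:**
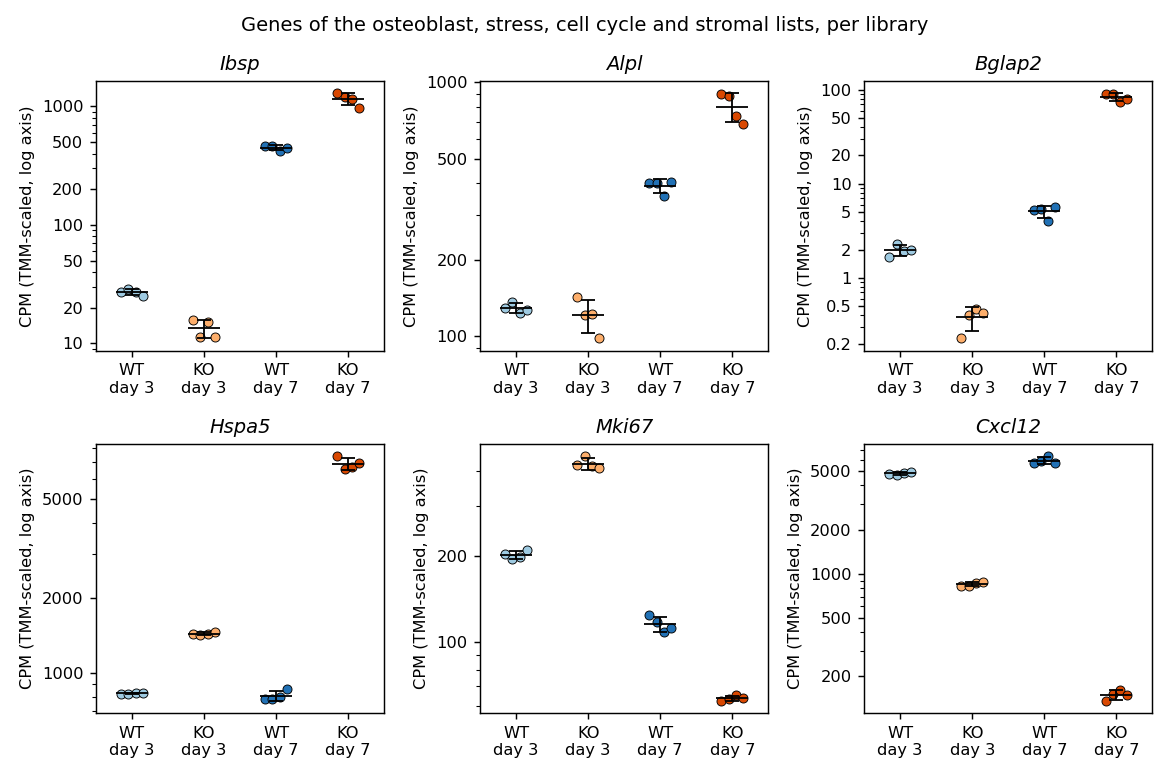
CPM on a log axis of Ibsp, Alpl, Bglap2, Hspa5, Mki67 and Cxcl12 in each of the 16 libraries (points), with the mean (bar) and SD (error bar) of the 4 libraries of each group. Hspa5 reaches 6912 CPM in the day 7 group labelled KO against 807 CPM in the WT day 7 group, and Mki67 is highest in the day 3 group labelled KO (422 CPM).

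In WT cells the comparison of day 7 with day 3 asked which RNAs follow osteogenic culture, with day, medium and seeding density changing together. Of 25 osteoblast genes 20 rose and 3 fell (median log2 fold change 1.15, camera adjusted p = 4.1e-10, and 0.03 with an estimated correlation). All 37 cell cycle genes fell (median -0.85, camera adjusted p = 1.7e-30, and 0.00019 with an estimated correlation). Ibsp rose from 27.0 ± 1.55 to 450 ± 21.2 CPM, a log2 fold change of 4.06 ± 0.10 (n = 4 libraries per group). Alpl rose from 129 ± 5.83 to 391 ± 23.9 CPM and Sp7 from 77.7 ± 1.96 to 173 ± 12.5 CPM. Tsc22d3 (GILZ) and Fkbp5, both direct targets of the glucocorticoid receptor, rose from 42.6 ± 1.51 to 356 ± 5.88 CPM and from 33.2 ± 0.472 to 165 ± 0.625 CPM, with dexamethasone present at day 7 only. Angptl4, an inhibitor of lipoprotein lipase, fell from 276 ± 8.20 CPM by a log2 fold change of -3.79 ± 0.05.

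The widest rises in WT cells were in Ngfr, the low-affinity nerve growth factor receptor, from 0.0305 ± 0.0389 to 16.3 ± 2.86 CPM, and the kinase gene Wnk2, from 0.0389 ± 0.065 to 10.4 ± 1.39 CPM. Zbtb16 (PLZF), a glucocorticoid-induced transcription factor, rose from 0.0503 ± 0.045 to 14.7 ± 0.546 CPM. Fap, a fibroblast surface protease, rose from 0.769 ± 0.133 to 35.4 ± 4.08 CPM, Lgi2 from 0.155 ± 0.127 to 14.2 ± 1.05 CPM and the sulfotransferase Sult1a1 from 0.27 ± 0.138 to 17.2 ± 1.80 CPM. Besides Angptl4, the widest falls were in Col10a1, the collagen of hypertrophic cartilage (-3.55 ± 0.18), the small GTPase gene Rnd1 (-2.91 ± 0.10), Artn, a ligand of the RET pathway (-2.75 ± 0.09), the glutamate transporter Slc1a1 (-2.69 ± 0.08) and Col2a1 (-2.52 ± 0.07).

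Other osteoblast genes that rose were the parathyroid hormone receptor Pth1r from 2.04 ± 0.312 to 29.5 ± 2.48 CPM and Dmp1, an osteocyte matrix protein, from 0.638 ± 0.0861 to 9.16 ± 2.07 CPM. Among cell cycle genes Mki67 fell from 202 ± 6.54 to 116 ± 7.15 CPM. Glucocorticoid-responsive genes rose in 14 of 20 cases and fell in 3, 14 and 4 adjusted over the list alone (median 1.00, camera adjusted p = 4.6e-09, and 0.0026 with an estimated correlation). The IGF axis rose in 8 and fell in 5 of 16, 8 and 6 adjusted over the list alone (median 0.42, camera adjusted p = 2.3e-06, and 0.0021 with an estimated correlation). Igfbp2 rose from 1.16 ± 0.213 to 37.2 ± 2.53 CPM and Igf2, a growth factor, from 4.72 ± 0.192 to 55.7 ± 2.17 CPM. Interferon-stimulated genes rose in 23 of 25 and fell in 1 (median 1.75, camera adjusted p = 5.9e-06, adjusted p = 0.46 with an estimated correlation). Ifi44 rose from 1.13 ± 0.217 to 10.7 ± 2.03 CPM and the ubiquitin-like modifier Isg15 from 4.42 ± 0.531 to 28.8 ± 3.55 CPM.

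Wnt pathway genes rose in 12 of 23 cases and fell in 4 (median 0.64, camera adjusted p = 0.0033, adjusted p = 0.18 with an estimated correlation). Axin2, a feedback inhibitor induced by Wnt signalling, rose by 3.82 ± 0.08 on the log2 scale. Collagen genes rose in 18 of 29 and fell in 7, 20 and 7 adjusted over the list alone (median 0.31, camera adjusted p = 0.0033, adjusted p = 0.3 with an estimated correlation). Lum (lumican) was at least 70.9-fold higher, from 0 counts at day 3. The lists that went down were ribosome biogenesis (24 of 30 lower, 1 higher, camera adjusted p = 0.00066, adjusted p = 0.23 with an estimated correlation) and cholesterol synthesis (15 of 23 lower, 2 higher, camera adjusted p = 0.00079, adjusted p = 0.19 with an estimated correlation). The BMP and TGF-beta pathway went down too (15 of 27 lower, 9 higher, 16 and 9 adjusted over the list alone, camera adjusted p = 0.0074, adjusted p = 0.18 with an estimated correlation). Chemokine genes fell in 11 of 17 and rose in 6 (camera adjusted p = 0.0053, adjusted p = 0.18 with an estimated correlation). Ptgs2, an inducible cyclooxygenase, fell from 36.4 ± 1.03 to 6.70 ± 1.11 CPM. Glycolysis (12 of 20 lower, 3 higher, camera adjusted p = 0.012, adjusted p = 0.62 with an estimated correlation) also went down. So did oxidative phosphorylation (19 of 28 lower, 2 higher, camera adjusted p = 0.014) and the integrated stress response (13 of 21 lower, 4 higher, camera adjusted p = 0.027), both with an adjusted p = 0.62 with an estimated correlation.

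In total 9063 genes changed between the days in WT cells, 4356 up and 4707 down, and 1303 by at least 2-fold (793 up, 510 down; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05). Of the 14 list calls 4 held with an estimated correlation, those of osteoblast, cell cycle, glucocorticoid-responsive and IGF axis genes. The macrophage list was not called between the days in WT cells (4 of 18 higher, 8 lower, camera adjusted p = 0.43). Other list counts were the same adjusted over the list alone except hypoxia (2 higher and 8 lower, 7 lower adjusted over the list alone). The split of called genes depends on scaling, since 48.1% were higher with trimmed mean scaling and 34.5% with the authors' library sizes.

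In the libraries labelled KO the comparison of day 7 with day 3 asked the same of the other genotype. Of 25 osteoblast genes 23 rose and 1 fell (median log2 fold change 2.10, camera adjusted p = 5.8e-13, and 0.013 with an estimated correlation). All 37 cell cycle genes fell (median -2.32, camera adjusted p = 6e-57, and 5.8e-06 with an estimated correlation). Bglap2 rose from 0.382 ± 0.107 to 83.6 ± 8.06 CPM and Ibsp from 13.4 ± 2.38 to 1156 ± 135 CPM (log2 fold changes 7.78 ± 0.13 and 6.43 ± 0.12, n = 4 libraries per group). Mki67 fell from 422 ± 19 to 63.6 ± 1.35 CPM and Rrm2 from 194 ± 4.30 to 19.4 ± 1.96 CPM. Tsc22d3 rose from 35.3 ± 2.39 to 518 ± 19.3 CPM and Fkbp5 from 96.7 ± 2.15 to 314 ± 10.5 CPM. Macrophage markers fell in 14 of 18 cases and rose in 1 without a call as a list (camera adjusted p = 0.25).

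The widest rises were in Thbs4, a matrix thrombospondin of tendon (0.028 ± 0.0401 to 11.4 ± 1.16 CPM) and the BMP family ligand Bmp8a (0.0545 ± 0.0545 to 16.4 ± 1.56 CPM). The lipid carrier Apod (0.0699 ± 0.0714 to 19.8 ± 1.73 CPM), H19 (0.729 ± 0.288 to 191 ± 58 CPM), Bglap2 and Car9 (0.443 ± 0.147 to 70.3 ± 19.3 CPM) followed. Mcam (CD146), a marker of perivascular stromal cells, fell from 27.6 ± 1.26 to 1.35 ± 0.153 CPM, Nes (nestin) from 55.1 ± 3.05 to 4.21 ± 0.194 CPM and Angptl4 from 137 ± 2.76 to 7.14 ± 0.879 CPM. The proliferation genes Iqgap3 and Mybl2 fell as well (-3.32 ± 0.06 and -3.27 ± 0.07).

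All 23 unfolded protein response genes rose (median 1.37, camera adjusted p = 1.6e-23, and 0.0012 with an estimated correlation). Hspa5 rose from 1434 ± 16.4 to 6912 ± 381 CPM. Contractile genes fell in 11 of 14 and rose in 2 (median -1.57, camera adjusted p = 1.6e-10, and 0.034 with an estimated correlation). Acta2, smooth muscle actin, fell from 4187 ± 70.6 to 892 ± 43.3 CPM and Tagln (transgelin) from 740 ± 14.1 to 139 ± 12.8 CPM. Glucocorticoid-responsive genes rose in 13 of 20 and fell in 6 (median 1.54, camera adjusted p = 0.00017, and 0.042 with an estimated correlation). Interferon-stimulated genes rose in 24 of 25 and fell in 0 (median 3.84, camera adjusted p = 2.7e-09, adjusted p = 0.19 with an estimated correlation). Usp18 rose from 0.51 ± 0.336 to 36.0 ± 7.57 CPM and Oas1a from 0.18 ± 0.186 to 9.14 ± 2.54 CPM.

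Collagen genes rose in 19 of 29 and fell in 7 (median 0.52, camera adjusted p = 0.00012, adjusted p = 0.1 with an estimated correlation). Fmod rose from 76.1 ± 9.62 to 1673 ± 68.5 CPM. Chondrocyte genes rose in 10 of 13 and fell in 2 (median 1.47, camera adjusted p = 0.0054, adjusted p = 0.1 with an estimated correlation). Adipocyte genes rose in 10 of 17 and fell in 4 (median 0.20, camera adjusted p = 0.017, adjusted p = 0.13 with an estimated correlation). Klf15, a glucocorticoid-induced transcription factor, rose from 0.886 ± 0.246 to 44.8 ± 0.881 CPM. Matrix proteases rose in 13 of 17 and fell in 4 (median 0.69, camera adjusted p = 0.016, adjusted p = 0.15 with an estimated correlation). Mmp13 rose from 17.6 ± 1.02 to 188 ± 22.7 CPM. Osteoclast markers rose in 6 of 7 and fell in 1 (median 1.23, camera adjusted p = 0.014, adjusted p = 0.13 with an estimated correlation). The cathepsin Ctsk rose from 6.67 ± 0.334 to 109 ± 5.57 CPM. The integrated stress response rose in 20 of 21 and fell in 1 (median 0.93, camera adjusted p = 3.1e-08, adjusted p = 0.11 with an estimated correlation). Hypoxia-responsive genes rose in 13 of 15 and fell in 1 (median 1.01, camera adjusted p = 0.0016, adjusted p = 0.4 with an estimated correlation). The IGF axis rose in 8 of 16 and fell in 3 (median 0.25, camera adjusted p = 0.023, adjusted p = 0.1 with an estimated correlation).

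Going down in the libraries labelled KO were ribosome biogenesis (28 of 30 lower, 2 higher, camera adjusted p = 0.0011, adjusted p = 0.15 with an estimated correlation) and oxidative phosphorylation (25 of 28 lower, 1 higher, camera adjusted p = 0.00017, adjusted p = 0.3 with an estimated correlation). The BMP and TGF-beta pathway followed (20 of 27 lower, 7 higher, camera adjusted p = 0.0017, adjusted p = 0.099 with an estimated correlation). Cholesterol synthesis (18 of 23 lower, 2 higher, 3 higher adjusted over the list alone, camera adjusted p = 0.00063, adjusted p = 0.13 with an estimated correlation) fell too. So did chemokines (11 of 17 lower, 4 higher, camera adjusted p = 0.0015, adjusted p = 0.1 with an estimated correlation). Ctgf, a TGF-beta and YAP target, fell from 386 ± 30.6 to 49.2 ± 1.91 CPM, while Bmp2, an inducer of osteoblasts, rose from 0.546 ± 0.255 to 17.8 ± 1.54 CPM. Altogether 10771 genes changed, 5477 up and 5294 down, and 2867 by at least 2-fold (1682 up, 1185 down; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05). Of the 19 list calls 5 held with an estimated correlation (osteoblast, cell cycle, unfolded protein response, contractile and glucocorticoid-responsive), and the other list counts were the same adjusted over the list alone.

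The interaction asked whether the change from day 3 to day 7 differed between the libraries labelled KO and WT. All 23 unfolded protein response genes had a higher change in the libraries labelled KO (median interaction 1.52 on the log2 scale, camera adjusted p = 6.2e-37, and 9.5e-05 with an estimated correlation). Of 14 contractile genes 12 had a lower and 0 a higher change there (median -1.62, camera adjusted p = 1.5e-18, and 0.0056 with an estimated correlation). Hspa5 stood at 825 ± 4.38 and 807 ± 38.6 CPM in the WT groups but rose from 1434 ± 16.4 to 6912 ± 381 CPM in those labelled KO. Its interaction was 2.30 ± 0.05 (n = 4 libraries in each of 4 groups). For Alpl the interaction was 1.12, with log2 fold changes between the days of 1.60 in WT and 2.72 in the libraries labelled KO, and for Mki67 it was -1.92 ± 0.06. Plin4, a lipid droplet protein, fell from 7.78 ± 0.323 to 2.30 ± 0.67 CPM in WT and rose from 1.08 ± 0.053 to 24.2 ± 2.37 CPM in the libraries labelled KO.

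Bglap2 (6.40 ± 0.23) and Car9 (7.57 ± 0.97) were among the 6 highest interactions with Plin4, Bmp8a, Thbs4 and Cyb5r2. In the WT groups Thbs4 stayed at 0.0343 and 0.0475 CPM and Cyb5r2 at 0.0575 and 0 CPM. The lowest were Wnk2 (-5.92 ± 0.93), the synaptic scaffold gene Shank2 (-5.79 ± 0.17), Apcdd1, an inhibitor of Wnt signalling (-5.45 ± 0.12), and Pappa, a protease of IGF-binding proteins (-5.44 ± 0.12). The kinase Hunk (-4.69 ± 0.12) and Ankrd1 (-4.66 ± 0.25) came next. Pappa rose from 6.42 ± 0.289 to 40.1 ± 3.53 CPM in WT and fell from 112 ± 7.57 to 16.2 ± 2.39 CPM in the libraries labelled KO.

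The cell cycle list had 35 of 37 lower and 2 higher (median -1.38, camera adjusted p = 3.9e-31, and 9.5e-05 with an estimated correlation). Among contractile genes Cnn1 (calponin) rose from 69.7 ± 4.44 to 80.1 ± 2.49 CPM in WT but fell from 106 ± 2.74 to 18.8 ± 1.58 CPM in the libraries labelled KO. Integrated stress response genes were higher in 20 of 21 cases, 21 adjusted over the list alone (median 1.12, camera adjusted p = 6.3e-15, adjusted p = 0.054 with an estimated correlation). Osteoblast genes were higher in 16 and lower in 4 of 25, 17 and 4 adjusted over the list alone (median 1.12, camera adjusted p = 4e-04, adjusted p = 0.15 with an estimated correlation). Interferon-stimulated genes were higher in 23 of 25 (median 1.77, camera adjusted p = 6.1e-06, adjusted p = 0.35 with an estimated correlation). Hypoxia-responsive genes were higher in 12 of 15 cases and lower in 1 (median 1.01, camera adjusted p = 1.1e-05, adjusted p = 0.33 with an estimated correlation).

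Chondrocyte genes (9 of 13 higher, 0 lower, median 1.46, camera adjusted p = 0.0015, adjusted p = 0.097 with an estimated correlation) were higher in the interaction. Osteoclast markers (5 of 7 higher, 0 lower, median 1.68, camera adjusted p = 0.0015, adjusted p = 0.097 with an estimated correlation) were too. Adipocyte genes were higher in 10 of 17 cases and lower in 4 (median 0.46, camera adjusted p = 0.004, adjusted p = 0.1 with an estimated correlation). Col10a1 fell from 12.7 ± 1.09 to 1.08 ± 0.287 CPM in WT and rose from 2.39 ± 0.872 to 9.73 ± 1.22 CPM in the libraries labelled KO. Glycolysis was higher in 13 of 20 and lower in 1 (median 0.48, camera adjusted p = 0.012, adjusted p = 0.49 with an estimated correlation). Oxidative phosphorylation was lower in 21 of 28 and higher in 0 (median -0.26, camera adjusted p = 0.01, adjusted p = 0.49 with an estimated correlation). The interaction was called for 8889 genes, 4378 positive and 4511 negative, and was at least 2-fold for 2189 (1241 and 948; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05). Of the called genes 49.3% were positive, against 58.2% with the authors' library sizes and 43.8% with total counts only. Of the 12 list calls 3 held with an estimated correlation: unfolded protein response, cell cycle and contractile. Over the 5 comparisons together 67 list calls were made and 18 held with an estimated correlation, and 133 of 145 list counts were the same adjusted over the list alone. In the interaction the counts that moved besides those given were those of cytosolic ribosomal proteins (17 higher and 17 lower, 15 and 16 adjusted over the list alone) and the Wnt pathway (9 and 8, 10 and 8 adjusted over the list alone). Of the sex-linked genes 0 were higher and 1 lower, 0 and 0 adjusted over the list alone.

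**Figure D3:**
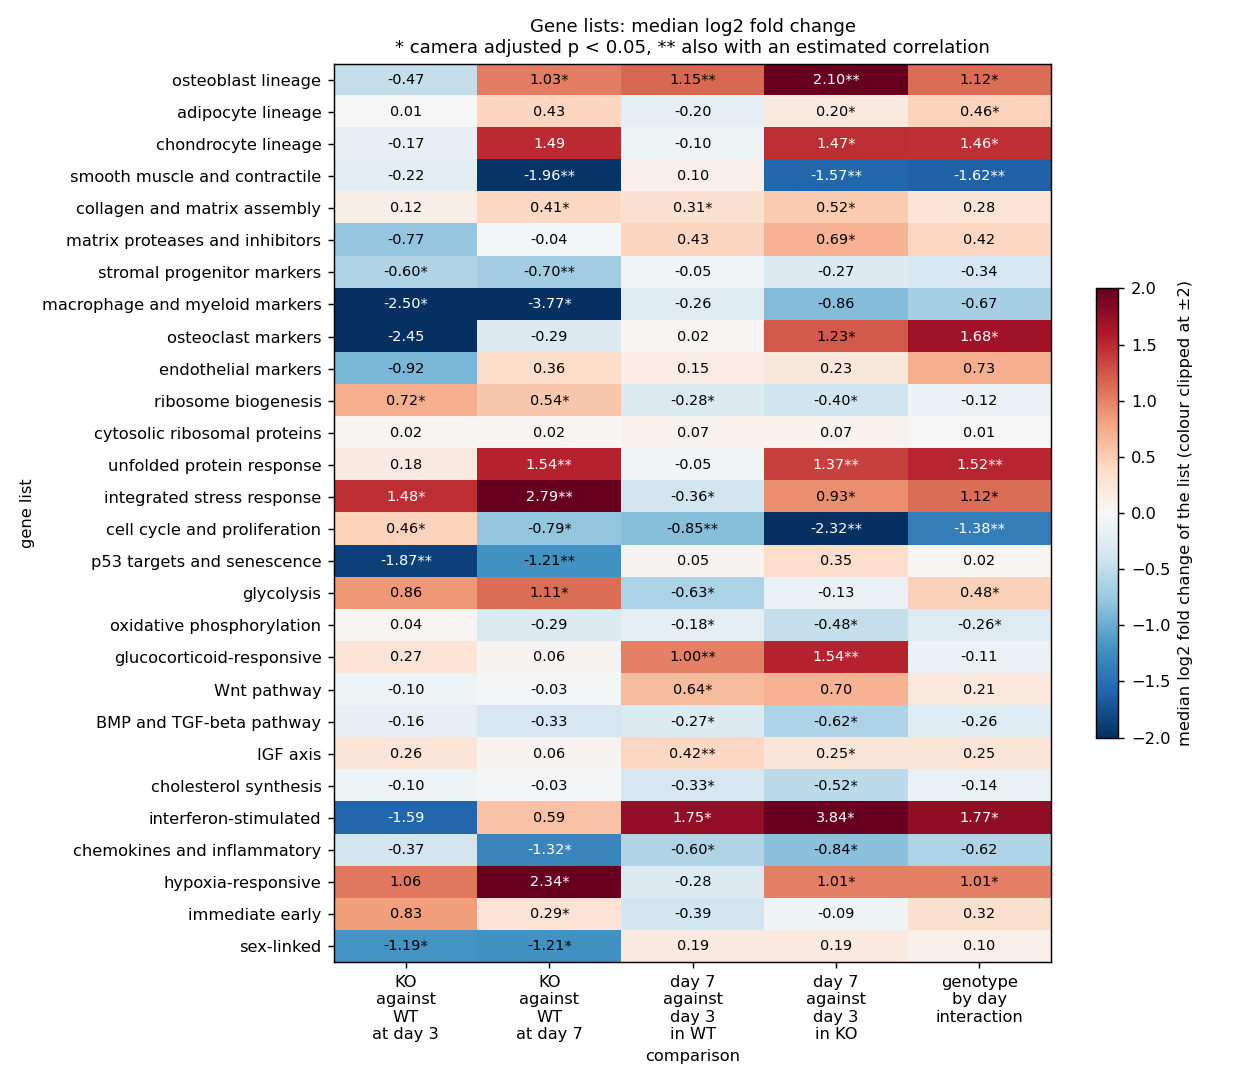
Median log2 fold change of the measured members of each of the 28 tested gene lists (vertical axis) in the 5 comparisons (horizontal axis), coloured from -2 to 2, with * for a camera adjusted p under 0.05 and ** where the call also held with an estimated correlation. The p53 and senescence list is low in both genotype comparisons (-1.87 and -1.21), and the unfolded protein response is high at day 7 between genotypes (1.54) and between the days in the libraries labelled KO (1.37).

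The genotype differences at day 3 and day 7, which share no library, were correlated across genes (Pearson correlation 0.836, Spearman correlation 0.756), genes not being independent replicates. Of the genes past 2-fold, 1047 were higher at both days (217 for independent lists), 1640 lower at both (393) and 75 opposite. Fabp4, Ccng1 and Cxcl12 were lower and Trib3, Vldlr and Postn higher at both days. The changes from day 3 to day 7 in WT and in the libraries labelled KO had a Pearson correlation of 0.533 and a Spearman correlation of 0.523. Of the genes past 2-fold, 483 rose in both (99 for independent lists), 239 fell in both (45) and 82 went opposite ways. Ibsp, Tsc22d3, Zbtb16 and Igf2 rose and Angptl4 and Rrm2 fell in both genotypes, while Plin4 and Col10a1 fell in WT and rose in the libraries labelled KO.

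Differences between genotypes were also arranged by chromosome. The median log2 fold change of the genes of chromosome 13 was 0.82 at day 3 and 0.70 at day 7, and those of chromosomes 4 and 18 were both 0.68 at day 3 and 0.61 at day 7. Chromosome 7 stood at 0.41 and 0.28. Chromosome 11 stood at -0.43 and -0.46, chromosome 12 at -0.46 and -0.45, and chromosome 6, which carries Zfp384, at -0.38 and -0.31. On chromosome 13, 83.7% of 492 genes were higher in the libraries labelled KO at day 3, and on chromosome 12, 21.3% of 484 genes were. Between the days, the medians of the autosomes spanned 0.12 in WT and 0.17 in the libraries labelled KO, against 1.28 between genotypes at day 3 and 1.16 at day 7. With the genes of these 7 chromosomes left out, an alternative chosen after the data were seen, 7212 of the other 8513 genes differed at day 3, and 2166 by at least 2-fold.

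**Figure D4:**
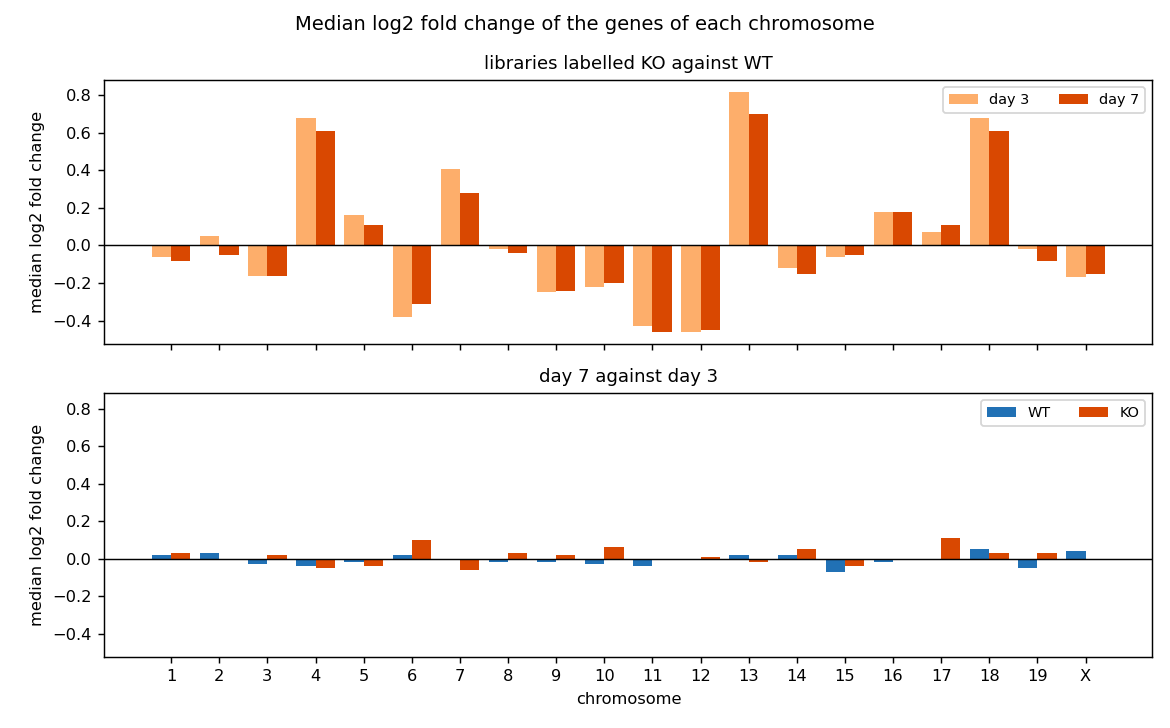
Median log2 fold change of the genes of each autosome and of the X chromosome (bars), between libraries labelled KO and WT at day 3 and day 7 (upper panel) and between the days in WT and in libraries labelled KO (lower panel). Chromosome 13 stands at 0.82 and chromosome 12 at -0.46 between genotypes at day 3, while between the days all autosomes lie within a span of 0.12 in WT and 0.17 in libraries labelled KO.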

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

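Of the tests in this part, those of a wrong scaling factor, of chance placing on chromosomes, of a wrong label, of the scaling of Zfp384, of its exons, of parts of chromosomes and all 3 on the p53 and senescence list were chosen after the result was seen.

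The change from day 3 to day 7 differed between the libraries labelled KO and WT for 8889 genes by the interaction test, and for 12 gene lists by camera. The adjusted p was 6.2e-37 for the unfolded protein response, 3.9e-31 for the cell cycle and 1.5e-18 for contractile genes, and these 3 calls held with an estimated correlation (adjusted p = 9.5e-05, 9.5e-05 and 0.0056). The other 9 did not hold. The camera adjusted p was 6.3e-15 for the integrated stress response (adjusted p = 0.054 with an estimated correlation), 6.1e-06 for interferon-stimulated genes (adjusted p = 0.35 with an estimated correlation) and 1.1e-05 for hypoxia-responsive genes (adjusted p = 0.33 with an estimated correlation). It was 4e-04 for osteoblast genes (adjusted p = 0.15 with an estimated correlation), and 0.0015 for chondrocyte and 0.0015 for osteoclast genes (both adjusted p = 0.097 with an estimated correlation). It was 0.004 for adipocyte genes (adjusted p = 0.1 with an estimated correlation), and 0.01 for oxidative phosphorylation and 0.012 for glycolysis (both adjusted p = 0.49 with an estimated correlation). For each pair of groups, fitted on its own libraries, 1 of the 35 splits, the real one, gave as many changed genes. Any other split mixes wells of both groups, so the difference between the groups enters the spread within them. A low count there follows from that, and 35 splits leave a chance division of these wells unlikely rather than excluded. The real splits called 11685 genes (genotype, day 3), 11354 (genotype, day 7), 9362 (days, WT) and 10384 (days, libraries labelled KO), and the highest of the other splits called 0 in each. For the interaction 1 of 100 splits, the real one, reached 8889, with 0 in the highest other. These draws mix wells of both genotypes and both days, so the differences of genotype and of day enter the spread within groups. They therefore cannot decide whether the interaction is more than a chance division of the wells. With 1 biological replicate per condition, these splits set groups against the spread between wells only, and chance differences between independent cultures are not excluded.

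Some single libraries stood apart from the other 3 of their group. Among 120 combinations of a gene or total and a group, 13 did, where chance alone gives about 1 in 20. In WT day 3, library 3 had Adipoq at 0.285 CPM (the others 0.071 to 0.101), Igf2 at 5 CPM (4.59 to 4.66) and Tnfsf11 at 4.17 CPM (3.38 to 3.49). There library 1b had Mmp13 at 289 CPM (267 to 269) and library 4 had Cd68 at 11.6 CPM (12.5 to 12.6). In the day 3 group labelled KO, library 8 had Acan at 1.76 CPM (2.13 to 2.2), Ncl at 1510 CPM (the others at 1420) and Tnfrsf11b at 60.4 CPM (57.7 to 58.2). In WT day 7, Alpl was at 355 CPM in library 10b (401 to 406) and Ppp1r15a at 13.5 CPM in library 10 (11 to 11.2). Library 11 had Ptprc at 0.905 CPM (1.3 to 1.32) and Ncl at 758 CPM (712 to 714). In the day 7 group labelled KO, library 13 had Myc at 176 CPM (164 to 166). Without WT day 3 library 3 the genotype difference of Adipoq at day 3 was no longer called (-1.109, edgeR adjusted p = 0.157).

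Between genotypes, 6 autosomes had a median over 0.3 from that of all autosomal genes in the same direction at both days: 4, 7, 13 and 18 higher and 11 and 12 lower in the libraries labelled KO. The tables argue against 1 wrong scaling factor, which would move all chromosomes alike, since the autosomal medians spanned 1.28 at day 3 and 1.16 at day 7. They argue against chance placing of changed genes, with a permutation p of 1e-04, the smallest that 10000 shuffles can give, and a farthest median of 0.82 against 0.2 in the shuffles. The 6 autosomes are what a copy number difference between the cultures would need. All 8 parts of 5 of them, and 7 of 8 of chromosome 12, had the same sign at both days. These autosomes were picked by their medians in the same data, so the signs of their parts largely follow from that choice. Every part of chromosomes 6 and 10, outside the 6, was lower at both days as well. Copy number of whole chromosomes may be involved, as a hypothesis from RNA alone, to which the parts add no support. An effect of the genotype on the genes of these chromosomes stays open and untested.

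Zfp384 RNA was not lower in the libraries labelled KO at either day. The tables argue against a single library with a wrong label, since 16 of 16 libraries correlated best with the others of their own group (mean r of at least 0.995, at most 0.967 with another group), which does not bear on an exchange of whole groups. They argue against scaling, since the log2 fold change ran from 0.09 (total counts, day 3) to 0.99 (the authors' library sizes, day 7). A targeted allele whose RNA keeps the counted exons could give such values and stays open, because 0 exons of the gene had counts of their own here. Around the locus, 36.8% of 144 genes within 10 Mb were called past 2-fold at day 3 against 30.6% of genes of like expression elsewhere (permutation p = 0.045). At day 7 it was 38.2% against 32.6% (permutation p = 0.067). The genes elsewhere were drawn from all autosomes, while chromosome 6 as a whole was lower (median -0.38 and -0.31, against -0.48 and -0.44 for the genes within 10 Mb). The draws therefore do not separate the locus from its chromosome, and a segment of the donor strain can be neither shown nor excluded.

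The list of p53 targets and senescence genes was lower in the libraries labelled KO at both days, with 12 of 16 members lower and 4 higher. The tables argue against copy number of the chromosomes its genes lie on as the whole cause, since the list was still called lower with each chromosome centred (camera adjusted p at most 1.6e-12). They argue against less Trp53 RNA, whose log2 fold change was -0.03 ± 0.04 at day 3 and 0.01 ± 0.04 at day 7. Genes chosen after their values were seen moved unevenly: the p53 target Cdkn1a (p21) fell by 2.86 ± 0.04 at day 3 but dropped by 0.37 ± 0.04 at day 7, Mdm2, a p53 target and inhibitor, fell by 2.67 ± 0.04 and 2.13 ± 0.03, and Cdkn2a, whose product ARF restrains Mdm2, rose by 1.47 ± 0.04 and 1.19 ± 0.04 (edgeR adjusted p at most 1.65e-10). The day 7 fall of Cdkn1a may depend on the scaling, since the authors' library sizes put the median log2 fold change of all genes at 0.55 there. A change that arose in 1 culture apart from the genotype may account for the lower list. It cannot be told apart from the genotype, because each condition had 1 biological replicate, and the protein was not measured.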

How the results depend on the processing

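The tests with the authors' library sizes, with each chromosome centred and without the genes of shifted chromosomes were chosen after the result was seen, and the other settings were planned. No paired analysis was possible because the groups share no replicate numbers. A glmTreat test against a 1.5-fold change called 5733 genes (genotype, day 3), 5939 (genotype, day 7), 1872 (days, WT), 4164 (days, libraries labelled KO) and 2794 (interaction), fewer because it asks for a larger change. By it Zfp384, at 0.161 and 0.409, was not called (glmTreat adjusted p = 1 at both days). Without the genes of the 7 shifted chromosomes, which leaves 8513 of the genes to test, the counts were 7212, 7237, 5765, 6807 and 5647 in the same order, and 2166, 2385, 813, 1819 and 1391 at 2-fold or more. With an estimated correlation 1, 5, 4, 5 and 3 lists were called. With fry, which asks only whether a list moves on balance, 25 lists were called at day 3 and 27 at day 7 between genotypes, 26 between the days in WT and 26 in the interaction. With each chromosome centred 11 lists were called between genotypes at day 3, the added ones being unfolded protein response, adipocyte, osteoclast and interferon-stimulated genes. Immediate early genes lost their call at day 7 (camera adjusted p = 0.069) and the p53 and senescence list gained one between the days in the libraries labelled KO (camera adjusted p = 0.049). Under centring 3 genes reversed at day 3 without being called there: Rps23 (-0.085), Uqcrfs1 (-0.053) and Atp5a1 (-0.005). They lie on chromosomes 13 and 18, whose medians are what centring removes. The correlation of the genotype differences, 0.836, moved by more than its error of 0.0031 to 0.84 with the stricter filter, 0.832 with limma-voom, 0.83 with centring and 0.832 without shifted chromosomes, and the cause was not tested. Total counts of changed genes stayed within 1.5 times the main count under every other setting. Counts by direction moved further with the authors' library sizes, where lower genes went from 5850 to 3220 at day 3 and from 5974 to 2969 at day 7, and higher genes from 5618 to 9087 at day 7, since with those sizes the median log2 fold change is 0.49 at day 3 and 0.55 at day 7, against 0 and -0.03. Of 705 results for named genes, 702 kept direction and call with DESeq2, 702 with limma-voom, 703 with RLE factors, 701 with total counts only, 693 with centring and 607 with glmTreat. Most of these genes were named because they were called in the same data, so a kept call largely follows from that choice. Apart from Zfp384, named genes were not checked with the authors' library sizes. The setting without a filter moves nothing, since the filter removed 0 genes. Leaving out each of the 16 libraries in turn gave 11439 to 11711, 11422 to 11602, 8592 to 9217, 10516 to 10765 and 8645 to 8913 genes. It gave 7 to 9, 14 to 15, 14 to 14, 19 to 20 and 12 to 13 lists. At 2-fold or more it gave 3900 to 3928, 4112 to 4162, 1295 to 1308, 2830 to 2879 and 2147 to 2203 genes. For the named genes, leaving out 1 library ended 50 calls, made 4 and reversed 0, and the genes concerned were Adipoq (genotype, day 3), Sox9 (genotype, day 7), Lck, Ptprc and Rpl30 (days, WT), Cd68, Ddx3y and Xist (days, libraries labelled KO) and Ddx3y, Derl3, Eng and Lum (interaction). Zfp384 ran from 0.151 to 0.177 at day 3 and from 0.387 to 0.436 at day 7, and the correlation from 0.833 to 0.836. With these depths a gene below about 0.0179 CPM over a group of WT day 3 libraries is at the floor of 3 counts.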

Other observations

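The medians over parts of chromosomes given here were chosen after the result was seen. Sfrp1 and Sfrp2, secreted inhibitors of Wnt signalling, rose from day 3 to day 7 in WT and fell in the libraries labelled KO. Sfrp1 was at 271 ± 10.03 CPM in WT and 31.95 ± 1.88 CPM in the libraries labelled KO at day 3, and at 525 ± 40.95 and 10.9 ± 1.16 CPM at day 7, an interaction of -2.50 ± 0.09 (edgeR adjusted p = 1.55e-17, n = 4 libraries in each of 4 groups). Sfrp2 rose from 536.5 ± 14.2 to 779 ± 45.8 CPM between the days in WT and fell from 354 ± 8.6 to 97.4 ± 5.64 CPM in the libraries labelled KO. Wif1, a further inhibitor, was lower in the libraries labelled KO at both days (-5.12 ± 0.23 and -3.42 ± 0.12). Other inhibitors went the other way: Sfrp4 was at 0 counts in the WT day 3 libraries and at least 273-fold higher in those labelled KO, and stood at 0.0132 against 7.92 ± 1.21 CPM at day 7. Dkk2 stood at 0.0177 against 1.52 ± 0.301 CPM at day 3 and 0.0412 against 4.98 ± 1.1 CPM at day 7. The Wnt list as a whole was not called between genotypes (11 of 23 higher and 10 lower at day 3, camera adjusted p = 0.84, and 10 and 10 at day 7, camera adjusted p = 0.25).

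In the IGF axis Stc2, an inhibitor of the protease Pappa, rose from 0.0958 ± 0.0174 CPM in WT to 26 ± 2.29 CPM in the libraries labelled KO at day 7, and Igfbp6 from 3.94 ± 0.375 to 54.7 ± 3.24 CPM. Igf1 fell from 41.5 ± 2.32 to 12.4 ± 1.6 CPM there. The list moved both ways between genotypes (8 of 16 higher and 7 lower at day 7, camera adjusted p = 0.52). The metallothionein genes Mt1 and Mt2, which bind zinc and copper, were higher in the libraries labelled KO at both days, and Mt2 rose from 8.18 ± 0.653 to 212 ± 16.8 CPM at day 7. They belong to the glucocorticoid list, which was not called between genotypes (8 of 20 higher and 9 lower at day 7, camera adjusted p = 0.25). Of the pair of genes that control osteoclast formation, Tnfsf11 (RANKL) was at 3.62 ± 0.367 and 3.74 ± 0.21 CPM at day 3 and rose from 2.4 ± 0.378 to 4.05 ± 0.367 CPM at day 7. Tnfrsf11b (osteoprotegerin) was higher in the libraries labelled KO at both days (0.67 ± 0.05 and 0.47 ± 0.05).

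Some chromosomes differed between genotypes in part of their length, in regions chosen after their values were seen. On chromosome 9 the 87 genes that start from 34488731 to 48654297 had a median of -0.85 at day 3 and -0.93 at day 7, while the 149 that start from 94517864 to 109095436 stood at 0.05 and -0.05. On chromosome 16 the 67 genes that start from 87354185 to 98062512 stood at 0.53 and 0.39, and the 117 that start from 15550986 to 27307641 at -0.01 and 0.00. Among genes placed on the Y chromosome Ddx3y was near 0 in the libraries labelled KO (0.0967 CPM at day 3), Kdm5d stood at 22 against 50.1 CPM, and Erdr1, also chosen after its values were seen, at 170.5 ± 12.3 against 69.5 ± 3.11 CPM. No explanation was tested for these values.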
